A study of Mus musculus with 6 samples.

How the data were processed

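Total RNA of Raw 264.7 cells was amplified, labelled with biotin and hybridised to 6 whole-transcript arrays, 3 labelled IL-33 and 3 labelled PBS, per the labels' protocols. Cells were grown in medium with 10% serum, starved and treated in 2% serum, and the time of treatment is not given in the sources used here. The table the authors deposited holds 1 log2 expression value per probe set and array. The values were made with RMA (background correction, quantile normalization and median polish of probe intensities), per the submitters' processing notes, whose version and settings are not given in the sources used here. RMA makes the distributions of arrays alike, so a change shared by most genes would not be seen, and it compresses differences of probe sets near the background or the top of the scale. The table has no detection calls or background values, so no probe set was called absent. No 2 arrays held identical values.

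Of 41345 probe sets, 25335 had a row in the platform annotation used here. Of these, 23521 carried exactly 1 gene symbol and 1814 carried several, from which no gene was named. The remaining 16010 were unnamed here, 190 of them control probe sets. Symbols were checked through Entrez IDs against a RefSeq gene table of assembly GRCm38.p6; 23477 of the 23521 matched and 0 symbols changed. No build was named for the array, so no coordinates are printed. The 22180 genes were each represented by the probe set with the highest mean over all 6 arrays; 1082 genes had more than 1. Of 15 further probe sets of changed genes, 11 moved in the same direction.

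Groups were taken from the sample titles. The deposited log2 values were fitted as they stand with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient for the group, no covariates, no filter on dim probe sets), with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are IL-33 label minus PBS label on the log2 scale, and folds are 2 to that power or its inverse. The levels of different probe sets were not compared. The 31 gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The lists held 590 genes, of which 543 were measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

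The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Named were the 10 largest rises and the 10 largest falls among genes that passed with non-overlapping groups, leaving out genes without an official symbol. Of each list, up to 4 members that passed with the largest change were named, or up to 2 with the smallest p where none passed. The receptor chains and Nfkbia, Tnf, Il6, Il1b and Ccl2 were to be named whatever their values. The 6 changed genes without an official symbol, 4 higher and 2 lower, were left out of the named genes.

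Both groups carry replicate numbers 1 to 3, and nothing states that a number marks a shared culture or day. The numbers were not taken as pairs. The alternatives were 2 filters on dim genes, a further quantile normalization, centring on the 75th percentile, the mean of all probe sets of a gene, the replicate number as a block, a trended and robust prior variance (for lists, camera with a trended variance), array weights, all probe sets, and leaving out each array.

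The fit was tested on simulated data for the IL-33 against PBS comparison, with the means of the 22180 genes, variances drawn from the posterior of the fit, independent genes and 200 changed genes in each of 20 simulations. It recovered 61.2% of genes with a log2 change of 0.5 and 95.2% of those with a change of 1, and 5.11% of calls were unchanged genes. With no change, 0 genes were called. The simulated variances came from the same fit, so these gene-level rates take its prior variance as right and do not test it. A list shifted by 0.25 passed in 20 of 20 simulations with either correlation setting. Genes were independent there, so this does not show how a list of correlated genes would fare. In the real data the estimated correlation was 0.072 for the interferon list and 0.128 for the osteoclast list. It was 0.012 for the matrix protease list and -0.023 for the sterol list, near and below the preset. The other lists that passed at the preset had estimates above it. Unadjusted camera p still rose from 0.001467 to 0.03513 for the matrix protease list and from 0.001046 to 0.02524 for the sterol list. Correlation alone thus does not account for every list lost in that setting.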

Results

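Gene expression was measured in Raw 264.7 cells, a mouse monocyte and macrophage line, after starvation and culture in medium with 2% serum. Some arrays were labelled IL-33, a cytokine of the IL-1 family given at 50 ng/ml, and the others PBS. Each group held 3 arrays, and each array gave log2 values for 41345 probe sets, of which 22180 genes were tested. The highest value of an array lay between 13.62 and 13.66 (log2), and array medians lay between 5.31 and 5.36. Across genes, arrays of the same group correlated at r = 0.9972 to 0.9980 and arrays of different groups at r = 0.9967 to 0.9971. The first principal component held 50.9% of the variance of genes at or above the median mean value and separated the groups. The second held 16.7%, and on it the array labelled IL-33 replicate 1 lay furthest from the others. Arrays give no count depth, so the number of arrays limits the precision, and the median standard error of a log2 difference was 0.073. Nothing stated whether the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

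The comparison asked how expression in these cells differed with and without IL-33. Interferon-induced genes such as Mx1 and Ifi214 and the growth factor gene Csf2 were higher in the arrays labelled IL-33, by 2.80-fold, 2.31-fold and 2.23-fold. The IL-1 family gene Il1f9, the chemokine gene Cxcl3 and the protease gene Mmp12 were lower there, by 3.47-fold, 3.18-fold and 2.31-fold. All directions are those of the sample titles. The array names in the sample descriptions read the other way, with the letters IL on the arrays labelled PBS and the letter P on those labelled IL-33. "Rose" and "fell" therefore mean higher or lower in the arrays labelled IL-33, and every direction would turn if the labels were exchanged.

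At an adjusted p under 0.05 (limma, Benjamini-Hochberg), 131 of 22180 genes changed, with 61 higher and 70 lower. Of these, 67 changed at least 1.5-fold, with 27 higher and 40 lower, and 20 changed at least 2-fold, with 6 higher and 14 lower. The 3 values of one group did not overlap those of the other in any of the 131 genes. That was so for 20.3% of all genes, where chance gives 10%. At an unadjusted p under 0.05, 2920 genes passed, where 1109 would by chance. Leaving out 1 array left fewer calls in every case: 19, 36 and 16 without PBS replicates 1, 2 and 3, and 83, 15 and 19 without IL-33 replicates 1, 2 and 3. Of these, 26.3% to 41.7% were higher, against 46.6% of the 131. With a prior variance both trended on intensity and robust to outliers 1000 genes passed, among genes at or above the median mean value 760 passed, and over all probe sets other than controls 17 passed, with 4 higher and 13 lower.

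The gene with the largest rise was Trim30d (Entrez gene 209387), a tripartite motif protein. Its log2 value was 5.38 ± 0.20 (SD, n = 3) in the arrays labelled PBS and 7.41 ± 0.12 (SD, n = 3) in those labelled IL-33, a 4.09-fold rise. The interferon-induced gene Mx1, which the gene table used here lists as a transcribed pseudogene, rose 2.80-fold from 4.73 ± 0.20 to 6.21 ± 0.08 (SD, n = 3 each). Ifi214 and Ifi208, members of the interferon-inducible p200 family, rose 2.31-fold and 1.78-fold. The membrane proteins Ms4a4c and Ms4a6c rose 2.46-fold and 1.88-fold. Csf2, which encodes the growth factor GM-CSF, rose 2.23-fold from 6.79 ± 0.20 to 7.95 ± 0.16 (SD, n = 3 each). The other probe set of Csf2 had a smaller log2 difference of 0.58. Cp, the copper-binding ferroxidase ceruloplasmin, rose 2.03-fold. Cd69, an early activation antigen of leukocytes, rose 1.89-fold, and the lipase gene Lipg rose 1.78-fold. Adjusted p for these 10 genes lay between 0.00285 and 0.0312 (limma). Trim30d, Mx1 and Ifi214 passed whichever array was left out, whereas Ms4a4c, Cp, Ms4a6c and Lipg were each lost in 5 of the 6 such fits, Csf2 in 4, Cd69 in 3 and Ifi208 in 6.

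The gene with the largest fall was Il1f9 (Entrez gene 215257), which encodes the IL-1 family cytokine IL-36 gamma. Its log2 value was 10.35 ± 0.02 (SD, n = 3) in the arrays labelled PBS and 8.56 ± 0.22 (SD, n = 3) in those labelled IL-33, a level 3.47-fold lower. Cxcl3, a neutrophil chemoattractant, was 3.18-fold lower and fell from 6.65 ± 0.11 to 4.98 ± 0.25 (SD, n = 3 each). Stfa3, a stefin A cysteine protease inhibitor, was 2.99-fold lower with an adjusted p of 0.0470 (limma). The inhibitors of serine proteases Serpinb2 and Serpinb9b were 2.41-fold and 2.17-fold lower. The other probe set of Serpinb9b had a smaller log2 difference of -0.75. The chemokine Ccl6 was 2.40-fold lower, at 7.89 ± 0.10 against 6.63 ± 0.04 (SD, n = 3 each). S100a8, a calcium-binding protein of myeloid cells, was 2.36-fold lower, and Mmp12, the macrophage elastase, was 2.31-fold lower. Pdpn, the membrane glycoprotein podoplanin, and Osbp2, an oxysterol-binding protein, were each 2.25-fold lower. Adjusted p for the 9 genes other than Stfa3 lay between 0.00285 and 0.0133 (limma). Il1f9, Cxcl3, Serpinb2, Serpinb9b, Ccl6, Mmp12 and Pdpn passed whichever array was left out, while S100a8 was lost in 2, Osbp2 in 4 and Stfa3 in 5 of the 6 such fits.

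**Figure D1:**
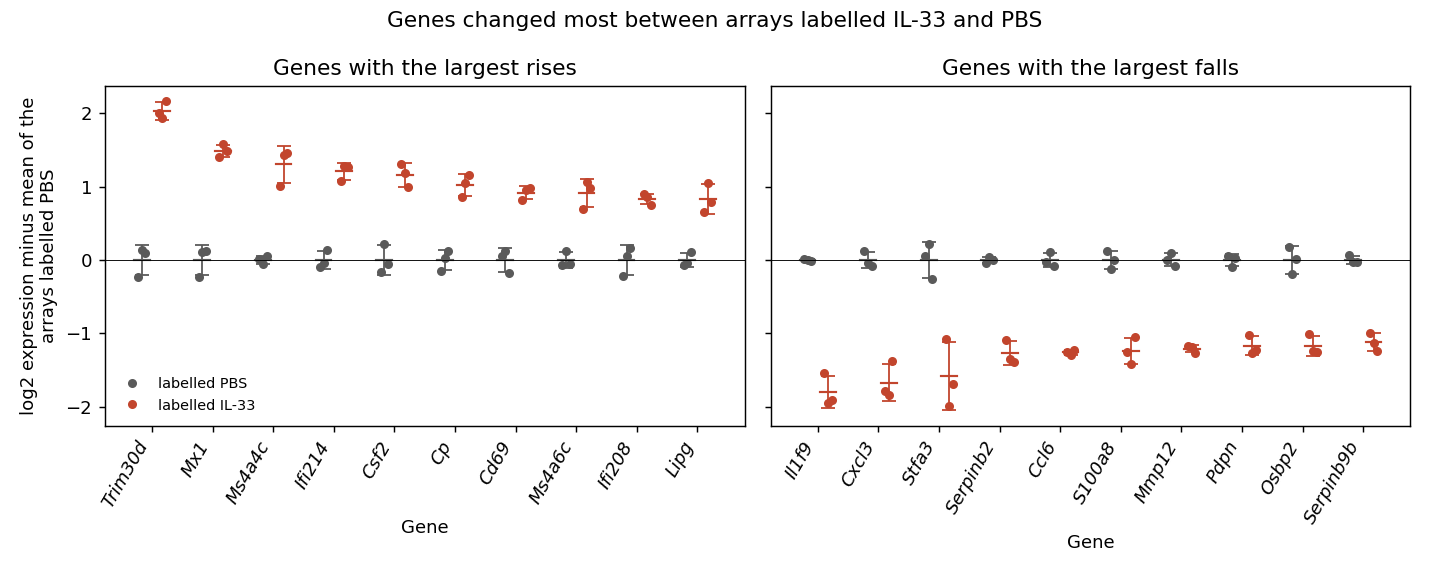
Per-array log2 expression of the 10 genes with the largest rises (left) and falls (right), on the vertical axis as the difference from the mean of the arrays labelled PBS, with 3 points per group and bars for the mean ± SD. The groups do not overlap in any of these genes, and the means differ by 2.03 for Trim30d and by -1.80 for Il1f9 (log2).

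Interferon-stimulated genes were higher as a group. All 30 measured members had a difference above 0, with a median log2 difference of 0.25. Of these, 8 rose and 22 did not pass, and 27 were higher when adjusted over the list alone. Besides Mx1, the RNA-binding Ifit2 rose 1.54-fold, the nucleic acid sensor Zbp1 rose 1.44-fold and the interferon-gamma-induced GTPase Igtp rose 1.37-fold, with adjusted p of 0.0113, 0.0133 and 0.0288 (limma). The list passed the camera test with an adjusted p of 5.072e-28 at the preset inter-gene correlation, and the adjusted p was 0.058 with an estimated correlation. The chemokine Cxcl10, which interferons induce, rose 1.36-fold with an adjusted p of 0.0183 (limma). Of 17 antigen presentation genes 2 rose, the immunoproteasome subunit Psmb9 by 1.46-fold and the peptide transporter Tap1 by 1.26-fold, and 15 did not pass. Adjusted over the list alone 4 were higher and 2 lower, and the list did not pass camera, with an adjusted p of 0.0842.

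Genes of the osteoclast program were lower as a group. Of 25 measured members 5 fell, none rose and 20 did not pass, with a median log2 difference of -0.18. There were 12 lower members when adjusted over the list alone. Atp6v0d2, a proton pump subunit needed for osteoclast fusion, was 2.04-fold lower, and the gelatinase Mmp9 was 1.71-fold lower. The tyrosine kinase Src was 1.63-fold lower and Dcstamp, a fusion receptor, was 1.54-fold lower. The fifth, the chloride transporter Clcn7, had a log2 difference of -0.55 and is named after its values were seen. Nfatc1, the main transcription factor of the program, had a log2 difference of -0.01 with an adjusted p of 0.9498 (limma), and was likewise chosen after its values were seen. The list passed camera with an adjusted p of 4.507e-11 at the preset correlation, and the adjusted p was 0.1875 with an estimated correlation. Of 10 genes that repress osteoclast formation 1 fell, the transcription regulator Id2, which was 1.37-fold lower. Adjusted over the list alone 1 was higher and 1 lower, and the list did not pass camera, with an adjusted p of 0.7914.

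Matrix proteases and their inhibitors gave 4 members that fell, none that rose and 17 that did not pass. The median log2 difference was -0.07, with 7 of 21 members above 0, and it was -0.018 without PBS replicate 3 and -0.031 without IL-33 replicate 3. The 4 that fell were Serpinb2, Mmp12, the neutrophil collagenase Mmp8, which was 1.93-fold lower, and Mmp9, and 6 members were lower and 1 higher when adjusted over the list alone. Their list passed camera with an adjusted p of 0.007582 at the preset correlation, and the adjusted p was 0.218 with an estimated correlation. All 14 genes of the NRF2 and oxidative stress list had a difference below 0, with a median of -0.21. None of them passed over all genes, and 9 were lower when adjusted over the list alone. Sulfiredoxin, Srxn1, had a log2 difference of -0.35 with an adjusted p of 0.0510, and catalase, Cat, of -0.25 with an adjusted p of 0.105 (limma). The list passed camera with an adjusted p of 2.795e-07 at the preset correlation, and the adjusted p was 0.167 with an estimated correlation.

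The remaining 4 lists that passed camera held 1 gene that passed over all genes. Immediate early and MAPK feedback genes had a median log2 difference of -0.12, and 1 of 28 fell, the MAP kinase phosphatase Dusp1, which was 1.57-fold lower. Adjusted over the list alone, 9 were lower and 3 higher. Glycolysis and hypoxia genes had a median of -0.08, and none of 21 passed, with the mitophagy receptor Bnip3 at a log2 difference of -0.52 and an adjusted p of 0.0866 (limma). Sterol synthesis and uptake genes had a median of 0.09, and none of 14 passed, with Cyp51, a demethylase of cholesterol synthesis, at 0.20. The p53 targets and cell cycle inhibitors had a median of 0.08, and none of 16 passed, with the TNF receptor family gene Eda2r at 0.41. Adjusted p for these 4 lists was 0.007582, 0.007732, 0.007582 and 0.007732 with camera at the preset correlation. With an estimated correlation the adjusted p was 0.5455, 0.4085, 0.1956 and 0.3154, in the same order. Adjusted over the list alone, 1 glycolysis gene was lower, 1 p53 target higher and no sterol gene passed. The immediate early list did not pass without IL-33 replicate 2, nor the glycolysis list without that array or without PBS replicate 1. Without PBS replicate 3 the glycolysis median was -0.038, and among genes at or above the median mean value the p53 list had an adjusted p of 0.05358. No list of the 31 passed with an estimated correlation. By fry, which does not compare a list with other genes, 9 passed, among them the TGF-beta, chemokine and antigen presentation lists, with adjusted p of 0.001328, 0.002478 and 0.03335, while the immediate early and glycolysis lists did not, with 0.1307 and 0.1047. Other splits of the 6 arrays into 3 and 3 gave up to 5 lists at the preset correlation.

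Inflammatory cytokines and chemokines moved in both directions. Of 21 cytokines Csf2 rose, Il1a and Il1b, the alarmin and inflammasome cytokines of the IL-1 family, fell, and 18 did not pass. Il1a was 1.91-fold lower and Il1b 1.46-fold lower, with adjusted p of 0.0183 and 0.0285 (limma). Of 21 chemokines Cxcl10 rose, Cxcl3, Ccl6 and the monocyte attractant Ccl7, which was 1.40-fold lower, fell, and 17 did not pass. Among cytokines 3 were higher and 4 lower when adjusted over the list alone, and among chemokines 2 and 4. Camera gave an adjusted p of 0.4456 for cytokines and 0.1342 for chemokines. Of 28 NF-kB targets and feedback genes none passed over all genes, and 6 were lower and 4 higher when adjusted over the list alone. Their median log2 difference was 0.0065, their mean was -0.033, and camera gave an adjusted p of 0.993. Median, mean and test also differed in sign for the lymphocyte, Fc receptor, heat shock, pattern recognition and unfolded protein lists, none of which passed. Tnfaip3, an inhibitor of NF-kB signalling, had a log2 difference of -0.64 with an adjusted p of 0.0523, and the stress gene Gadd45b of -0.37 with an adjusted p of 0.0618 (limma).

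Most readouts of IL-1 family receptor signalling fixed beforehand did not pass, while Il1b passed and was lower. Nfkbia, the NF-kB inhibitor, differed by 0.07 ± 0.05 (log2, SE), and the cytokines Tnf and Il6 by -0.03 ± 0.05 and 0.08 ± 0.08 (log2, SE). The monocyte chemoattractant Ccl2 differed by -0.15 ± 0.05 (log2, SE). Adjusted p for these 4 genes lay between 0.272 and 0.866 (limma). Il1b, the other readout fixed beforehand, was 1.46-fold lower with an adjusted p of 0.0285 (limma). Tnf and Ccl2 had log2 levels of 13.07 and 12.95 in the arrays labelled PBS, near the upper end of the scale of these arrays. Il1rap, the accessory chain of the IL-33 receptor, differed by 0.29 ± 0.08 (log2, SE) with an adjusted p of 0.192, and the kinase Irak2 by 0.19 with an adjusted p of 0.1703 (limma). None of the 13 measured members of the receptor and signalling list passed, over all genes or adjusted over the list alone, and camera gave the list an adjusted p of 0.3968. The other chain of the receptor was not analysed here.

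Macrophage identity genes gave 1 rise, 1 fall and 18 members that did not pass. Fcgr1, the high-affinity IgG receptor, rose 1.41-fold and was also the only riser among 17 Fc receptor and phagocytosis genes. Gpnmb, a glycoprotein of lysosome-rich macrophages, was 1.36-fold lower. Among 20 alternative activation markers 1 fell, the beta-glucan receptor Clec7a, which was 1.43-fold lower. Among 21 pattern recognition receptors 1 fell, the lectin Clec4n, which was 1.85-fold lower. Among 16 adhesion genes the integrin Itga6 rose 1.29-fold, and among 19 lipid handling genes the fatty acid carrier Fabp4 was 1.26-fold lower. Of 21 unfolded protein and stress response genes the chaperone Dnajb9 was 1.29-fold lower, and Id2 was the single gene to fall among 15 of the TGF-beta and BMP response. Adjusted p for these 8 genes lay between 0.0192 and 0.0485 (limma). Adjusted over the list alone, 2 genes were higher and 2 lower in each of the macrophage, Fc receptor and pattern recognition lists, 5 and 4 in the adhesion list, and 3 and 4 in the lipid list. In the alternative activation list 2 were lower, and 1 in each of the unfolded protein and TGF-beta lists. Camera gave an adjusted p of 0.1481 for the TGF-beta list and of 0.3968 to 0.9957 for the others.

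No gene passed among 24 genes of S phase, 26 of G2 and mitosis, 17 of apoptosis and survival, 12 heat shock proteins and 11 chemokine and chemoattractant receptors. In these lists the smallest p belonged to Rfc3, Cenpe, Bcl2l11, Bag3 and Fpr2, with log2 differences of 0.21, 0.17, -0.35, -0.13 and 0.59 and adjusted p of 0.213, 0.202, 0.156, 0.332 and 0.0593 (limma). In these, 2 apoptosis genes were higher and 1 lower when adjusted over the list alone, 1 receptor was higher and 1 lower, and no gene of the other lists passed. Camera gave these lists adjusted p of 0.7006, 0.5106, 0.142, 0.9957 and 0.7006. Of the 45 genes that passed and were named by the rule fixed beforehand, which leaves out Clcn7, 10 passed whichever array was left out. The others were lost in 2 to 6 of the 6 such fits. Among the named genes that did not pass, 15 passed with the trended and robust prior variance.

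Markers of other cell types were measured beside these lists. None of 10 fibroblast markers and none of 10 endothelial and epithelial markers passed, with Col6a1 at a log2 difference of -0.19 and Vwf at -0.27. Of 11 mast cell and basophil markers 1 rose, the histamine-forming enzyme Hdc by 1.71-fold. Of 10 lymphocyte markers 1 rose, the immunoglobulin heavy chain Ighm by 1.57-fold. The other probe sets of Ighm did not all move with it, and the log2 difference was 0.15 when all its probe sets were averaged. Ighm was lost in all 6 fits without an array and in 3 of the 9 other alternatives. Hdc was lost in 5 and 2 of them. Hdc, Ighm and 1 endothelial or epithelial marker, which was lower, passed when adjusted over the list alone. Camera gave adjusted p of 0.3968, 0.3525, 0.8499 and 0.993 for the fibroblast, endothelial and epithelial, mast cell and lymphocyte lists.

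**Figure D2:**
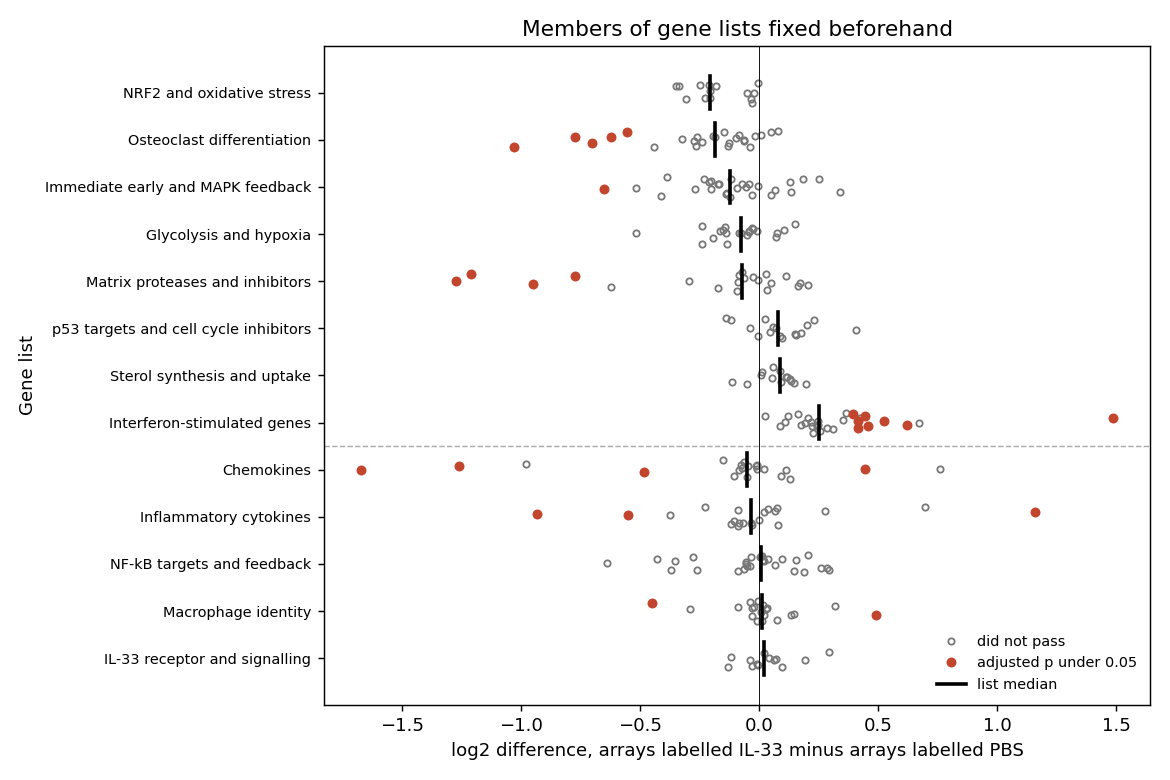
Log2 difference of each measured member (points) of the 8 gene lists that passed camera at the preset correlation (above the dashed line; 0 of 31 passed with an estimated correlation) and 5 that did not (below it), with filled points for genes at an adjusted p under 0.05 and black bars for list medians. All 30 interferon-stimulated genes lie above 0 and all 14 NRF2 genes below 0, while the NF-kB targets spread around a median of 0.0065.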

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

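The tests of related neighbouring genes, of intensity, of membership in other lists and of probe sets outside the genes tested were chosen after the results were seen, and those of the labels and of other splits before.

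Outside the 22180 genes tested, 1 of the 1814 probe sets annotated to several genes changed (adjusted over that class, limma). Probe set 17519673, shared by 4 genes and so not named, had a mean log2 value of 8.60 in the arrays labelled PBS and 7.13 in those labelled IL-33, with an adjusted p of 0.0107. None of the 15820 unlisted probe sets passed in limma, the only tool run on them. Of these, 1325 (8.38%) had an unadjusted p under 0.05, more than the share of 0.05 that chance gives. None of the 190 control probe sets passed in limma, where 8 (4.21%) had an unadjusted p under 0.05.

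The first pattern is the conflict between sample titles and array names. A test set beforehand asked whether NF-kB targets were lower, as exchanged labels may give, or higher, as the labels as given may give. Their median log2 difference was 0.0065 and camera with an estimated correlation gave an adjusted p of 0.9967. The test needed a pass in that setting, where 0 of the 31 lists passed, so it could hardly have decided either way. Adjusted over the list alone, 6 members were lower and 4 higher. Exchanged and correct labels cannot be told apart from this list. If the labels were exchanged, every direction in the results would turn, and every size would stay.

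The second pattern is the higher level of interferon-stimulated genes, whose camera test gave an adjusted p of 0.058 with an estimated correlation and so did not pass there. The interval and random lists below take genes as independent, so they do not bear on whether the list shifted. The rise was not limited to members with a neighbour of the same name root, as the 17 members without such a neighbour within 5 tested genes show. Their median log2 difference was 0.255, with a 95% bootstrap interval of 0.222 to 0.416. All 30 members of the list were already known to lie above 0. The interval therefore could not include 0 and is no test of shared signal. A name root is the part of a symbol before its first digit or hyphen. Relatives with other names were not left out, so signal shared with those stays open. A bias that depends on intensity is argued against because none of 10000 random lists matched on mean expression lay as far from 0 as the list's median of 0.252; their medians ran from -0.0854 to 0.102. The treatment itself, a component of the cytokine preparation and a difference in culture between dishes stay open and were not tested.

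The third pattern is the lower level of osteoclast genes, whose camera test gave an adjusted p of 0.1875 with an estimated correlation and so did not pass there. The same limit on independence holds for the values below. A bias that depends on intensity is argued against because none of 10000 matched random lists lay as far from 0 as the list's median of -0.183; their medians ran from -0.106 to 0.0965. The fall was not limited to members shared with other lists. The 20 members found in no other list had a median of -0.165, and 18 of them were below 0. Their 95% bootstrap interval was -0.299 to -0.0913. Only 3 of the 25 measured members lay above 0, so this interval was all but certain to lie below 0 and is no further test. A change within cells and a change in the share of fusing cells stay open and were not tested.

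The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. With limma at an adjusted p under 0.05, the real split gave 131 genes and the highest of the other splits 0. For genes changed at least 1.5-fold these values were 67 and 0, and for lists with camera at the preset correlation 8 and 5.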

How the results depend on the processing

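All alternatives were chosen before the data were examined. The 131 changed genes became 760 at or above the median mean (401 higher) and 296 at or above the 25th percentile. They became 1000 with a trended and robust prior variance (530 higher) and 17 over all 41155 probe sets other than controls (4 higher). Of the 131 genes, 119, 128, 131 and 14 were among these calls. Under the filters and over all probe sets, the number of tests and the rows that set the prior variance both changed. Which of these moved the counts, and what moved the count with the trended and robust prior, was not tested. With the replicate block, 21 genes passed (5 higher), all at least 1.5-fold, and 20 were among the 131; it changed no list's call. Same-numbered arrays' deviations correlated at 0.04, 0.0566 and 0.0194, all small but above 0. Those of different numbers correlated at -0.0747 to 0.035, and PBS replicate 3 correlated better with IL-33 replicate 1 (0.035) than with its own number. These values neither show nor exclude that the numbers mark pairs. Leaving out 1 array, which leaves fewer samples, gave 15 to 83 changed genes, 15 to 59 genes changed at least 1.5-fold and 6 to 9 lists. The 67 genes changed at least 1.5-fold lay between 65 and 88 under the filters, normalizations, averaging of probe sets, array weights and prior variance. The 8 lists became 0 with an estimated inter-gene correlation and lay between 7 and 9 in the other fits with all arrays. The p53 list was also lost at or above the median mean, and the immediate early and glycolysis lists by fry. Of the 45 genes that passed and were named by the fixed rule, 0 changed sign and 9 were lost in no alternative that tested them. Mx1 lay below the median mean and was not tested there. The median gene was lost in 5 of the 6 fits without an array. Of the named genes that did not pass in the main fit, 15 passed with a trended and robust prior variance. Such passes numbered 13 at or above the median mean, 5 at or above the 25th percentile and 3 with array weights. Medians near 0 of 13 lists that did not pass changed sign in 28 cases, for which the cause was not tested. Alternative activation markers had 0.01393 at or above the median mean, 0.008651 with averaged probe sets and 0.009419 with quantile normalization again. Pattern recognition receptors had -0.02344 at or above the median mean, fibroblast markers 0.00345 with quantile normalization again, heat shock proteins 0.001149 with centring, and T and B lymphocyte markers 0.002753 with array weights. Without 1 array, list medians ran from -0.03306 to 0.00724 for alternative activation markers, from -0.000388 to 0.03154 for pattern recognition receptors, from -0.02992 to 0.0219 for heat shock proteins and from -0.05499 to 0.01375 for T and B lymphocyte markers. They ran from -0.02858 to 0.05678 for cell cycle G2 and mitosis, from -0.007702 to 0.03186 for cell cycle S phase, from -0.03327 to 0.02844 for Fc receptors and phagocytosis and from -0.004179 to 0.04724 for IL-33 receptor and signalling. The range was -0.06202 to 0.005552 for lipid handling and foam cell genes, -0.004245 to 0.01039 for macrophage identity, -0.04392 to 0.01182 for mast cell and basophil markers and -0.02745 to 0.014 for NF-kB targets and feedback. The values used here carry no background level, so signal over background was not measured.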

Other observations

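The tests in this part were chosen after the changed genes were seen, and genes named here and not in the results were chosen after their values were seen. Among 625 groups of at least 5 tested genes sharing a name root, 5 held more changed genes than chance gives (Fisher's exact test, one-sided, Benjamini-Hochberg). They were the interferon-inducible Ifi genes (4 of 14 changed, adjusted p = 0.0006945), the Ms4a membrane proteins (4 of 20, 0.001429), the Il genes (6 of 78, 0.001429), the colony-stimulating factors and their receptors (3 of 8, 0.001724) and the matrix metalloproteinases (3 of 22, 0.0357). Members of a family are not independent, so these p-values are too small. Of the 4 changed Ms4a genes, Ms4a4c, Ms4a6c and Ms4a6b rose and Ms4a7 fell, with log2 differences of 1.30, 0.91, 0.81 and -0.93. Of the 4 changed Ifi genes, Ifi214, Ifi205 and Ifi208 rose, and Ifi27 fell with a log2 difference of -0.82.

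Within the IL-1 family, Il1f9 and its neighbour Il1f6, which encodes IL-36 alpha, both fell, with log2 differences of -1.80 and -1.06, as did the neighbours Il1a and Il1b. Around the colony-stimulating factors, Csf2 and the G-CSF receptor Csf3r rose, with log2 differences of 1.16 and 0.63, and the receptor subunit Csf2rb2 fell with -0.75.

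A hypothesis drawn from these groups was that changed genes lie next to one another in the genome. Of 130 changed genes with a place on a chromosome, 26 had another changed gene within 5 tested genes, against a mean of 8.25 in 10000 random sets matched on mean expression, of which 1 reached 26. Without pairs of the same name root the count was 12 against a mean of 8.06, and 2012 of the 10000 random sets reached it. For neighbours of different roots the count was thus above the random mean but within the range of chance. Genes of different roots can still be related, so the count does not separate unrelated neighbours from related ones. Signal shared between probe sets of related genes may contribute, and shared regulation stays open. Of the 16 neighbouring pairs, 12 moved in the same direction; Ms4a7 and Ms4a4c moved in opposite directions, which shared signal alone would not give.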
